A study of Drosophila melanogaster with 4 samples.

How the data were processed

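The data were 4 two-colour hybridisations of head RNA to spotted Drosophila cDNA slides. Per the labels' protocols, treated and control males came from parallel vials, RNA was isolated from pools of heads, and the 4 arrays were 4 biological replicates with the dyes exchanged on 2 of them. Labelled cRNA was made with T7 polymerase. Images were quantified by the authors with GenePix Pro 6.0 and normalized by ratio with Acuity 4.0, per the series' design text. That text also states that spots under 100 units of raw intensity and under a set multiple of the background were ignored in normalization. Spots were then kept only with under 3% of saturated pixels, no bad flag, a regression R2 between channels of at least 0.6 and a signal to noise ratio of at least 3. The authors took spots analysable on at least 3 of the 4 arrays to SAM 3.0. Ratio normalization applies 1 factor to an array, so it removes neither dye effects of single spots nor trends across the slide.

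The deposited values are log ratios, read here as log2. The log base, the centring and the direction of the deposited log2 ratio are not given in the sources used here. Column medians were -0.121, -0.379, -0.179 and -0.621 for replicates 1 to 4. Intensities per channel and spot flags were not used here, so the brightness behind a ratio is unknown and dye effects that depend on it were not modelled. The number of arrays limits the precision.

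Of 27648 spots, 15116 had 1 gene symbol in the platform annotation, 102 had several and 12430 had none. Gene IDs of 14894 spots matched a RefSeq gene table of assembly Release 6, which changed 0 symbols. A value on at least 1 array was present for 10449 spots, of which 5654 had 1 symbol. Neighbouring odd and even spots are duplicates: all 7609 such pairs with symbols carried the same symbol. Spots were averaged by gene symbol, and unnamed spots by duplicate pair. Values of duplicate spots correlated with r of 0.816, 0.818 and 0.718 on replicates 1, 2 and 4, and the median absolute difference was 0.138 to 0.168. No coordinates are given, because the array annotation names no build.

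The planned fit was limma with a treatment term of opposite sign for the exchanged dyes and a dye term, on genes with values on at least 3 of the 4 arrays. It had to be adapted, because the columns of replicates 1 and 3 were identical at 7643 of 7643 shared spots. Their mean entered once, with a treatment code of 0 because their labels disagree. The 4002 genes and spot pairs with a value in all 3 distinct sets were tested. The treatment term is then the difference between replicates 2 and 4 divided by 2, and the shared set serves only to estimate the spread, with 1 residual degree of freedom per gene. The spread was fully pooled by limma (infinite prior degrees of freedom), so each gene had the same SE of 0.465. Without replicate 2 or without replicate 4 this contrast has no residual degrees of freedom. The second result, chosen after seeing the data, was the mean of the 3 sets after median-centring, tested against 0 with limma. Adjusted p-values are Benjamini-Hochberg values from limma 3.58.1 in R 4.3.3, two-sided, with a threshold of 0.05. With 3 distinct sets from labelled biological replicates, p-values measure the spread between these sets.

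Fixed gene lists (30, of which 22 had at least 5 measured members) were tested with cameraPR at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. The lists, the thresholds, the other settings to try and the rule for named genes were written before the data were examined. The rule takes, per direction, the 10 genes of largest absolute log2 ratio among those past the threshold with the same sign on each array after turning. It fills up to 10 with the smallest unadjusted p, takes up to 4 members of each list by unadjusted p, and the chloride channel list in full.

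Position on the slide was corrected in an added alternative. The median of each of the 48 blocks of spots was subtracted per array, then a robust loess over rows of 24 spots and columns within the block (span 0.4), where a block held at least 30 values. Other alternatives were no dye term, columns not turned, median-centring, scale and quantile normalization, array weights, stricter and looser requirements for values, single spots as units, a threshold of 0.10, a 1.5-fold minimum, leaving out each replicate, all 4 columns as labelled, and leaving out spots beyond 3 on the log2 scale. A SAM-type statistic over all sign patterns was run on the mean of the 3 sets. It was not run on the planned contrast, which has 2 arrays of known orientation.

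The fits were tested on simulated data with 200 of 4002 genes changed by 1 or 2 on the log2 scale. The mean of 3 centred sets recovered 85.0% and 100% of them, with 18 false among 203 calls. The sets simulated for this fit shared no bias of position or dye. Their share of false calls therefore does not cover calls that such a bias would give in the real sets. The planned contrast recovered 0% and 0%, because an effect in the shared set then counts as spread. The simulated spreads differed between genes, whereas the real fit pooled the spread fully. There an effect in the shared set does not raise the SE of its own gene. This recovery therefore need not hold for the real fit. Had the shared set been known to be replicate 1, the planned contrast would have recovered 80.0% and 100%, with 17 false among 197 calls. Figures were drawn with matplotlib.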

Results

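Strychnine is a plant alkaloid and convulsant that blocks the vertebrate glycine receptor, a ligand-gated chloride channel. Gene expression was measured in heads of unmated Oregon-R males, a wild-type laboratory strain of Drosophila melanogaster, after 7 days on food with strychnine at 3.33 mg/ml. The comparison asked which head transcripts differed in amount from those of males kept on normal food. There was 1 group of 4 two-colour cDNA arrays, each a treated pool set against a control pool of its own biological replicate. The treated RNA carried Cy5 on replicates 1 and 2 and Cy3 on replicates 3 and 4. Of 27648 spots, 9356, 8894, 7647 and 9725 held a log2 ratio on replicates 1 to 4. The median log2 ratio was -0.121, -0.379, -0.179 and -0.621 in that order, and the SD over spots lay between 0.682 and 0.787.

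The columns of replicates 1 and 3 held the same value at each of the 7643 spots measured in both, although their labels give opposite dyes. They differed by less than any sampling noise and were counted as 1 sample, which left 3 distinct sets of values. These are named the shared set, replicate 2 and replicate 4. It is not known whether the shared set came from the array with treated RNA in Cy5 or from the one with it in Cy3. Nor do the labels say whether a positive value means more Cy5 or more treated RNA. A positive value is therefore not called an increase after strychnine below, except under a stated reading. The 3 sets correlated positively with each other across 4002 genes and spot pairs. After centring, 2199 units (54.9%) had 1 sign in all 3 sets, against 25% for unrelated sets. Pearson's r was 0.633 between the shared set and replicate 2, 0.411 between the shared set and replicate 4, and 0.478 between replicates 2 and 4. The matching Spearman's rho values were 0.665, 0.433 and 0.537. Replicates 2 and 4 carried opposite dyes, and genes are not independent replicates.

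**Figure D1:**
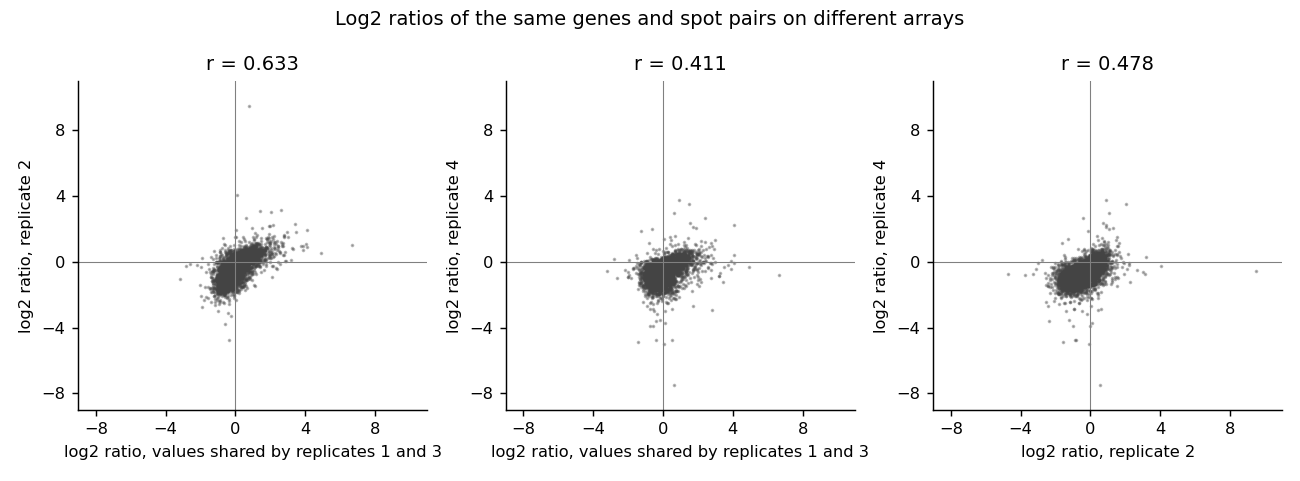
Log2 ratio of each of 4002 genes and unnamed spot pairs on one set of values (x axis) against another (y axis), each point being 1 gene or spot pair. The clouds rise from lower left to upper right in each panel, with r of 0.633, 0.411 and 0.478, the last between replicates 2 and 4 of opposite dye.

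Under the planned reading, a positive value means more Cy5. The treatment effect is then the part of the log2 ratio that changes sign with the dye, the difference between replicates 2 and 4 divided by 2. Of 4002 units tested (2027 named genes and 1975 unnamed spot pairs), 11 passed the threshold, 10 higher and 1 lower in treated heads. Named among them were 4 higher genes and 1 lower gene. In the values as deposited they kept no common sign on both arrays after turning. They therefore fall outside the rule for named genes and were chosen after their values were seen. The higher genes were glob1, which encodes a haemoglobin-like protein, Yp2, a yolk protein made mainly by females, 7B2, a chaperone of neuropeptide processing, and CG17724. Their log2 ratios were 2.47, 1.97, 1.95 and 1.96, each ± 0.465 (SE pooled over all units), with adjusted p of 0.000164 for glob1 and 0.0146 for the other 3. This SE is the same for each gene and does not measure the gene's own spread. The contrast itself sets 1 array against 1. For glob1 the SD over the 3 centred sets was 2.68. The lower gene was Su(var)3-3, a histone demethylase, at -1.999 ± 0.465 (SE; adjusted p = 0.0142).

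Each of these 5 values rested on a very low ratio on 1 array. On replicate 4 the centred log2 ratio was -4.40 for glob1, -4.16 for Yp2, -4.16 for CG17724 and -3.30 for 7B2. The same genes lay between -0.484 and 0.645 on the other sets. On this centred scale glob1 and 7B2, at 0.291 and 0.3495 on replicate 2, did keep the same sign after turning. Su(var)3-3 was at -4.37 on replicate 2, against -0.264 in the shared set and -0.131 on replicate 4. Duplicate spots on that array differed by over 1 log2 unit for each gene except 7B2, whose spots read -4.307 and -3.539. The spots of glob1 on replicate 4 read -8.29 and -1.75, and those of Yp2 read -1.72 and -7.84. With each array centred on its median, limma called 0 units, with 173 at an unadjusted p under 0.05, against 91 in the fit as deposited. Centring shifts the contrast of each unit by the same small amount (median over units 0.0995 before and -0.0217 after). The prior degrees of freedom went from infinite to 5.55 and the median SE from 0.465 to 0.265. Each gene's own spread therefore counted after centring, which it did not in the fit as deposited. A fit without replicate 1 or 3 keeps the shared set and gives it the dye of the replicate kept. Read as Cy3, without replicate 1, it left 3 of 3190 units past the threshold. Read as Cy5, without replicate 3, it gave 27.

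No other named gene passed in that contrast. The next higher genes by unadjusted p were Tim10, which encodes a chaperone of mitochondrial protein import, mub, apolpp, CG12617, CG11089, CG13124, CG8888, CG1090, SKIP and CG31826. Their log2 ratios ran from 1.63 for Tim10 (adjusted p = 0.121, SE 0.465) down to 0.982 for CG31826 (adjusted p = 1.00). The lower ones were CG3376, Noa36, CG10214, MYPT-75D, CG42613, GABPI, CG6693, CG3698, CG9313 and Elk, a voltage-gated potassium channel gene. They ran from -1.49 for CG3376 (adjusted p = 0.288) to -0.849 for Elk.

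Under the same reading, 1 of 22 fixed gene lists with at least 5 measured members stood apart from the other genes. The head fat body list had a median log2 ratio of 0.609 over its 5 members (cameraPR adjusted p = 0.00397). The call was lost with an estimated correlation (adjusted p = 0.960, resting on 1 residual degree of freedom) and with fry (adjusted p = 0.999). Yp2 was at 1.97, apolpp, the lipid carrier apolipophorin, at 1.31, and Mtp, a lipid transfer protein gene, at 0.609. Fbp2 was at 0.130 and Lsp2 at -0.331. Of the 5, 1 passed over all genes tested and 2 when adjusted over the list alone. Without Yp2 the median of the other 4 was 0.369 and the unadjusted p 0.0904. After centring each array the list's adjusted p was 0.105. The other 21 lists each had an adjusted p of 0.889.

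GluClalpha, a glutamate-gated chloride channel gene, was the 1 measured member of the ligand-gated chloride channel list, which covers the insect relatives of strychnine's vertebrate target. Its log2 ratio in the planned contrast was 0.0743 ± 0.465 (SE; adjusted p = 1.00), and its sign changed with centring of the arrays (-0.0470). Its centred log2 ratio was -0.336 in the shared set, -1.02 on replicate 2 and -0.922 on replicate 4, a mean of -0.758 ± 0.368 (SD, n = 3 sets; adjusted p = 0.0683). After the position correction that mean was -0.09996 (adjusted p = 0.836).

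If the deposited values are instead already treated over control, the effect is the mean of the 3 sets. This reading was listed as an alternative before the data were examined, and its use with centred arrays as a second result was chosen after seeing them. After each array was centred on its median, 350 of 4002 units lay apart from 0, 298 positive and 52 negative, of which 86 and 28 were named genes. The median size was 2.10-fold. The smallest adjusted p was 0.0411, so the count lies close to the threshold. Only 2 units passed without replicate 2, 1 of them among the 350. Without replicate 1 the shared set stayed in at the spots with a value on replicate 3, and 64 of 3190 units passed. With scale normalization 0 passed. With the values as deposited, limma called 0 units (1493 at an unadjusted p under 0.05). The median of all units was -0.399 before centring and -0.0165 after it.

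The named genes with the most positive means were yip7 and Jon65Aiii, which encode serine proteases of the gut, at 1.56 ± 0.499 and 1.34 ± 0.221 (SD, n = 3 sets). CG16826 was at 1.52 ± 0.272, and pea, an RNA helicase gene of the spliceosome, at 1.38 ± 0.385. CG30487, SmydA-7, CG14834, CG12493, CG10947 and CG43163 lay between 1.25 and 1.32. The most negative were CG10561 at -1.49 ± 0.855 and Cap-H2, a condensin II subunit gene, at -1.33 ± 0.604. Then came nahoda at -1.32, Swip-1 at -1.25 and spirit, a serine protease gene of the immune response, at -1.25. Vps36, an ESCRT-II subunit gene, was at -1.13 and Picot, a phosphate cotransporter gene, at -1.12. CG6567 was at -1.12, alphaSnap, a gene of vesicle fusion, at -1.11, and NC2alpha, a transcription corepressor gene, at -1.10. The adjusted p of these 20 genes lay between 0.0411 and 0.0499, and each had the same sign in 3 of 3 sets. All the positive genes among them lacked a value on replicate 3, and of the negative ones only Cap-H2 did. Spots without a value on replicate 3 had higher log2 ratios in general, with a median of -0.022 on replicate 2 against -0.478 for the rest. After a correction for position on the slide none of the 20 passed. Their means then lay between 0.337 and 1.00 on the positive side and between -1.17 and -0.332 on the negative side.

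**Figure D2:**
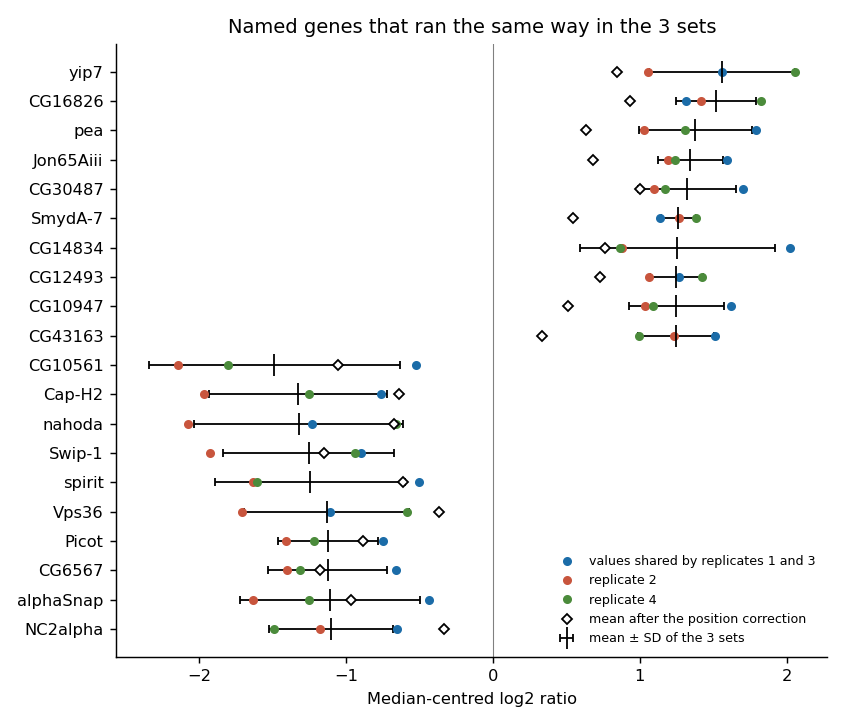
Median-centred log2 ratio (x axis) of the 20 named genes that ran the same way in the 3 sets. Coloured points are single sets, bars are mean ± SD (n = 3 sets), and open diamonds are means after the position correction. The diamond of CG43163 lies at 0.337 against a mean of 1.25, and that of Swip-1 at -1.15 against -1.25.

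No fixed list passed in the mean of the centred sets (0 of 22 by cameraPR, 4 at an unadjusted p under 0.05). Those 4, each with a negative median, were the lists of glycolysis and trehalose metabolism, cytochrome P450 genes, neuropeptides and their processing, and oxidative phosphorylation. List members are named genes, but they were ranked against all units, of which 1975 were unnamed pairs. Named genes made up 86 of the 298 positive calls and 28 of the 52 negative ones. Such a background could favour negative lists, which was not tested. Of all units 54.9% had 1 sign in all 3 sets, the share against which the counts of members by sign have to be read. In the glycolysis list 8 of 11 members were negative and 1 positive in all 3 sets, and the median was -0.426 (adjusted p = 0.123). After the position correction it was -0.0935, with an unadjusted p of 0.297. Pglym78, a phosphoglycerate mutase gene, was the 1 member past the threshold over all genes, at -0.932 ± 0.142 (SD, n = 3 sets). Adjusted over the list alone, 4 members passed: Pglym78, Gapdh1, Tpi and, on the positive side, Tps1. Gapdh1 was at -0.774 ± 0.0997 and Tpi at -0.762 ± 0.0670 (SD, n = 3 sets), with adjusted p of 0.0514 and 0.0515. Tps1 was at 0.755 ± 0.0836 (SD, n = 3 sets; adjusted p = 0.0523). The position-corrected means of Pglym78, Gapdh1, Tpi and Tps1 were -0.312, -0.279, -0.0559 and 0.311.

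The neuropeptide list had a median of -0.759 over 7 genes, of which 3 were negative in all 3 sets and none positive (adjusted p = 0.123). Pdf, the peptide of the clock neurons, passed at -0.811 ± 0.159 (SD, n = 3 sets; adjusted p = 0.0493). AstC was at -0.759 and Nplp1 at -0.826, and 3 members passed adjusted over the list alone. After the position correction the list median was -0.365 (unadjusted p = 0.0915), Pdf was at -0.246, AstC at -0.528 and Nplp1 at -0.365. The 16 cytochrome P450 genes, a family that includes detoxification enzymes, had a median of -0.412, with 7 negative and 1 positive in all sets (adjusted p = 0.123). None passed on its own. Cyp301a1 was at -0.689, Cyp9b1 at -0.599 and Cyp303a1 at -0.720. After the position correction the P450 median was -0.0457 and its unadjusted p 0.490, and these 3 genes were at -0.119, -0.0167 and 0.0598.

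Of 26 oxidative phosphorylation genes, 14 were negative and 3 positive in all 3 sets, where 54.9% of all units had 1 sign. Their median was -0.299 (adjusted p = 0.156), and -0.158 after the position correction (adjusted p = 0.135). The 1 member past the threshold, ND-51L2, was positive at 0.9177 ± 0.2997 (SD, n = 3 sets), and at 0.525 after the position correction (adjusted p = 0.178). ND-B22 was at -0.930 and ND-13A at -0.832 (-0.137 and -0.271 after the position correction), and none passed adjusted over the list alone. With an estimated correlation the adjusted p of each of these 4 lists was 0.843. Fry, which asks whether the genes of a list move on balance one way, gave 1 list past the threshold, the mitochondrial ribosomal proteins (adjusted p = 0.0213). Their median was -0.207 over 15 genes, of which 6 were negative and 3 positive in all 3 sets, and -0.123 after the position correction. That list did not pass with cameraPR (adjusted p = 0.483) or with an estimated correlation (adjusted p = 0.843).

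Heat shock proteins and chaperones had the most positive list median, 0.566 over 5 genes (adjusted p = 0.347). Hsp60C, at 1.02 ± 0.423, and Hsc70-5, at 0.955 ± 0.154 (SD, n = 3 sets), passed over all genes and over the list alone. Neither passed after the position correction (means of 0.594 and 0.394, adjusted p of 0.288 and 0.201). Hsc70-5 encodes a mitochondrial chaperone. DnaJ-1, a heat-inducible co-chaperone gene, was at 0.566. Among 13 glutathione S-transferase and UDP-glucuronosyltransferase genes, Ugt305A1 passed at 0.849 ± 0.210 (SD, n = 3 sets), and the list's median was -0.0402. The position-corrected mean of Ugt305A1 was 0.461 (adjusted p = 0.150). GstE14 was at -0.444 and GstD9 at -0.321. Of 9 proteasome genes 5 were positive and 2 negative in all sets, with a median of 0.282, which turned to -0.0709 after the position correction. Rpt4R was at 1.01 and Rpt3 at -0.788, and these 2 passed adjusted over the list alone. The 7 antimicrobial and humoral immunity genes had a median of -0.412, with Drsl5 at -1.17 and BomBc2 at -0.527, none past the threshold, and the list's median was -0.247 after the position correction. The 8 genes of neurotransmitter synthesis and transport had a median of -0.270. Hdc, the histidine decarboxylase gene, was at -0.893, Gs2 at -0.712 and Eaat2 at -0.702, none past the threshold. Position-corrected means were -0.303, -0.301 and -0.322 for these 3, -0.356 for Drsl5, 0.00534 for BomBc2 and 0.0428 for GstE14.

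**Figure D3:**
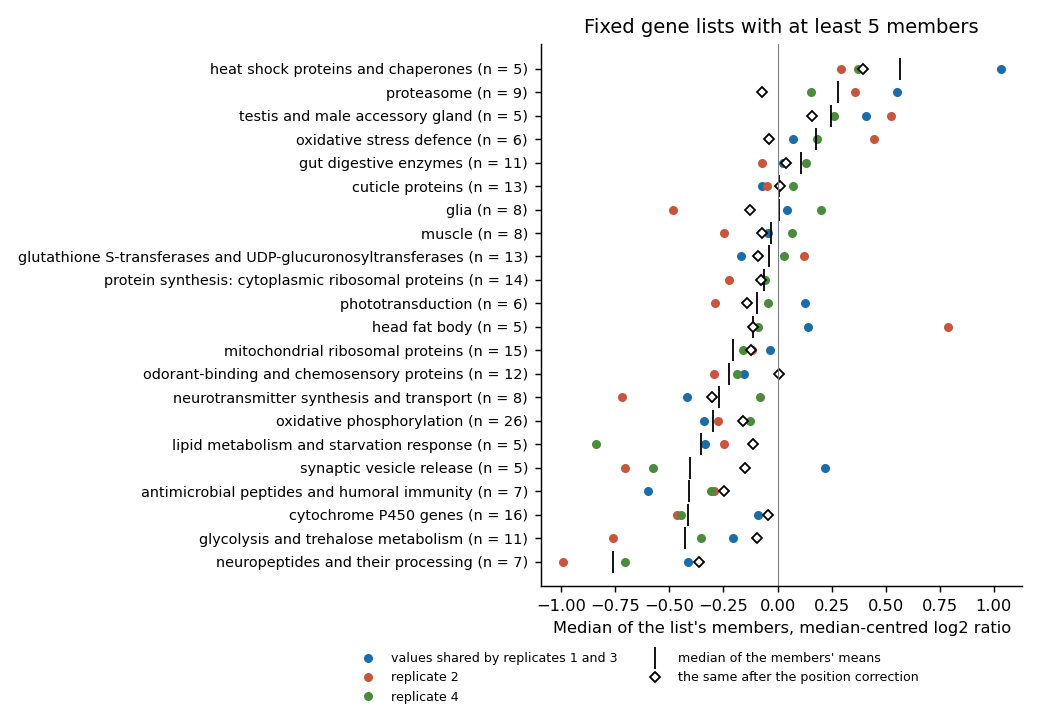
Median of each fixed list with at least 5 measured members (y axis) on the median-centred log2 scale (x axis), per set of values (coloured points), over the members' means (bars) and after the position correction (diamonds). Neuropeptides lie at -0.759 and heat shock proteins at 0.566, and the diamonds are at -0.365 and 0.394.

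Markers of tissues outside the head were measured as well. Of 11 gut digestive enzyme genes, yip7 and Jon65Aiii were positive past the threshold, while Jon66Cii was at -0.571. The gut list's median was 0.111, and 0.0395 after the position correction. Of 5 testis and accessory gland genes, Mst77F passed at 0.867 ± 0.113 (SD, n = 3 sets), and was at 1.24 after the position correction (adjusted p = 0.111). Mst85C was at -0.558 and Acp32CD at 0.453. The position-corrected means of Mst85C and Jon66Cii were 0.0960 and -0.184. That list's median was 0.249, and 0.160 after the position correction (adjusted p = 0.0609). The head fat body list had a median of -0.113 in the mean of the sets, with Fbp2 at 0.764 and Yp2 at -1.62, neither past the threshold over all genes. After the position correction Fbp2 was at 0.389 and Yp2 at -1.54. Muscle, glia and neuron markers had medians of -0.0306, 0.00517 and -0.161 over 8, 8 and 4 genes, and -0.0698, -0.129 and -0.0247 after the position correction.

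The median log2 ratio of a block of spots varied along the slide, in part alike on the 3 sets. The slide's 27648 spots were read as 48 blocks of equal size. Blocks held 21.0% of the variance of spots in the shared set, 30.0% on replicate 2 and 21.6% on replicate 4. Across the 48 blocks, medians of replicates 2 and 4 correlated with r of 0.732 (Spearman's rho 0.716), and with 1 block left out r stayed between 0.703 and 0.772. Averaged over the 12 runs of 4 blocks, the inner pair was higher than the outer pair in each of the 3 sets, though not in each run. On replicate 2 the mean of the block medians was -0.656, -0.0715, -0.265 and -0.811 by place in the run, each over 12 blocks with SD from 0.291 to 0.436. Neighbouring spots of different clones correlated with r of 0.525, 0.583 and 0.530 in the 3 sets. With block medians subtracted, 8 units passed in the mean of the 3 sets, all positive and none a named gene. With the local trend within blocks subtracted as well, limma called 0, with 814 at an unadjusted p under 0.05. These corrections were added after the data were examined.

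**Figure D4:**
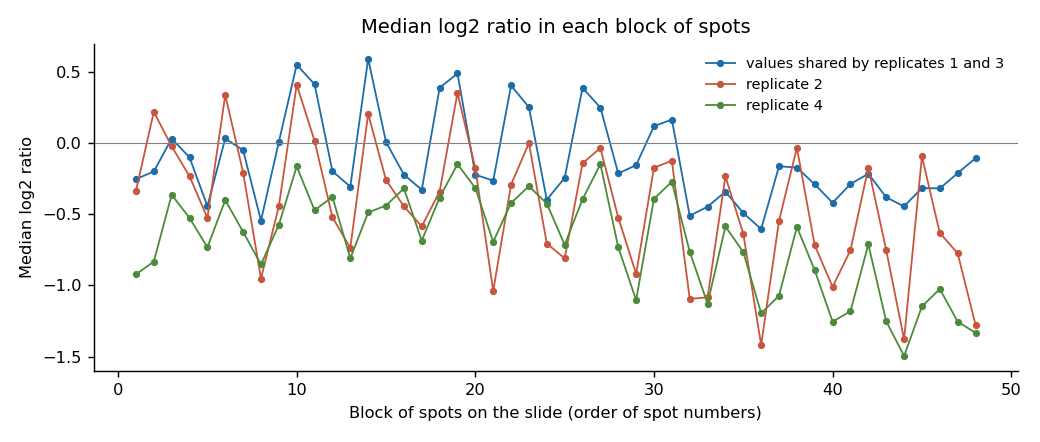
Median log2 ratio of the spots in each of the 48 blocks (y axis) against block number (x axis) for the 3 sets of values, as deposited. The lines follow each other over much of the slide, with their highest blocks at different places, and the block medians of replicates 2 and 4 correlate with r of 0.732.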

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

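Position corrections, fits with all 4 columns and the removal of extreme spots were chosen after seeing the data, as was each value for the mean of the 3 sets. The cause of a change was not tested unless stated. Leave-one-out fits of the planned contrast were possible only without replicate 1 or 3. These keep the shared set and assume a dye for it. The SAM-type statistic was not run on the planned contrast. Signal over background was not used here, so its limits are unknown.

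The planned contrast called 11 units. Without turning the columns, in values not centred (median of all units -0.399), it called 398 with the dye term. Of these 66 were positive and 332 negative, and it called 0 without that term. It called 2 without a dye term, also when units needed only 2 arrays of opposite dye. It called 0 with arrays centred, scaled or quantile normalized, with all 4 columns as labelled, with block medians or also the local trend subtracted, and with spots beyond 3 left out. Single spots gave 25 calls. Leaving out replicate 1 or 3, which reads the shared set as Cy3 or as Cy5, gave 3 and 27 calls. Of those calls 3 and 8 were among the 11. Array weights, values in all 4 columns, the 1.5-fold minimum and a threshold of 0.10 kept the count within 1.5 times.

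The mean of the 3 centred sets gave 350 calls. The count was 0 without centring, with scaling, for single spots and after the local trend was subtracted, and 8 after block medians alone, which are 8 of the 350. It was 35 with a dye term and 77 for units with values in all 4 columns. It was 572 with quantile normalization, 613 without spots beyond 3 (346 shared) and 1002 at a threshold of 0.10 (630 positive, 372 negative). The positive share was 85.1% of the 350. Leaving out a replicate gave 2 to 422, and without replicate 1 or 3 the shared set stays in. The SAM-type statistic called 340. Of 114 named genes past the threshold, 27 were picked by the rule for named genes. All of these lost the call without centring, with scaling, after either position correction and without replicate 2. With values in all 4 columns, and without replicate 1, only 13 of the 27 were tested, because the rest lacked a value on replicate 3. Each of these 13 lost its call in both settings. With a dye term 25 of the 27 lost it. None of these 27 changed sign.

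The count of fixed lists past the threshold in the planned contrast was 1. It was 0 without turning the columns, with centring or quantile normalization, after either position correction, without spots beyond 3, with an estimated correlation and with fry. Leaving out a replicate gave 0 to 1. It was also 0 with values in all 4 columns and with all 4 columns as labelled. In these 2 settings and without replicate 1, 19 lists were tested and the head fat body list had too few members, so its call was not tested there. In the mean of the 3 sets no list passed, and fry gave 1. The head fat body median of 0.609 turned to -0.492 without turning the columns, in values not centred. It was -0.113 in the mean of the centred sets. The correlation of replicates 2 and 4 across genes was 0.478, then 0.374 after block medians and 0.331 after the local trend.

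Without turning the columns, with and without a dye term, the planned values of genes named as higher became -1.51 for 7B2, -1.71 for CG17724, -1.69 for glob1, -1.999 for Yp2, -2.62 for Tim10, -0.295 for mub, -0.492 for apolpp, -0.334 for CG11089, -0.344 for CG13124, -0.359 for CG8888, -0.106 for SKIP, -0.0870 for CG31826, -0.0613 for Mtp and -1.14 for GluClalpha. These values were not centred, and the median of all units was then -0.399. In the mean of the centred sets mub, CG11089, CG13124, CG8888, SKIP, CG31826 and Mtp were positive, and the rest stayed negative. In the planned contrast GluClalpha was also -0.0470 with centring, -0.0407 with scaling, -0.190 without replicate 1 and 0.301 without replicate 3. In the mean of the 3 sets, Cyp303a1 was 0.0035 after block medians and 0.0598 after the local trend, Mst85C 0.126 and 0.0960, and Mtp -0.0430 and -0.113 (-0.0613 without centring). After the local trend GstE14 was 0.0428 and BomBc2 0.00534.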

Other observations

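The tests on the agreement of the arrays, on what remains after the position correction and on sign patterns were chosen after the results were seen. The predictions of the other tests were written before their results were seen. Among these, the test of position in the mean of the centred sets still used a correction and a result chosen after seeing the data.

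Several lists of nervous system and physiology genes were small on these arrays or near 0 in the mean of the centred sets. The 5 genes of synaptic vesicle release had a median of -0.405 but differed between sets. Their set medians were 0.222 in the shared set, -0.706 on replicate 2 and -0.574 on replicate 4. Voltage-gated and calcium-activated channel genes had a median of -0.258 over 3 genes and glutamate receptor genes -0.373 over 2. The 1 acetylcholine receptor gene measured, nAChRbeta1, was at -0.0330. Clock genes had a median of -0.382 over 3, activity-regulated and JNK pathway genes -0.466 over 3, phototransduction genes -0.0936 over 6 and haemocyte markers 0.497 over 3. Lipid metabolism genes had a median of -0.356 over 5 and oxidative stress defence genes 0.176 over 6. Cytoplasmic ribosomal proteins, cuticle proteins and odorant-binding proteins had medians of -0.0638, 0.00833 and -0.226 over 14, 13 and 12 genes. None of the tested ones passed. After the position correction the median was -0.149 for synaptic vesicle release, -0.0491 for glutamate receptors, -0.246 for clock genes, -0.202 for activity-regulated genes, -0.140 for phototransduction, 0.0915 for haemocyte markers and -0.114 for lipid metabolism. The sign turned for oxidative stress defence (-0.0384), odorant-binding proteins (0.00594) and nAChRbeta1 (0.171).

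Replicate 3 lacked a value at 1713 spots where replicate 1 had one, and 4 spots went the other way. The spots without a value on replicate 3 had higher log2 ratios: on replicate 2 their median was -0.022 against -0.478 for the rest, and on replicate 4 it was -0.316 against -0.715. The largest deposited value, 16.61 on replicate 2, was on a spot whose duplicate read 2.405.

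Replicates 2 and 4 correlated positively across genes although their labels exchange the dyes. Block medians of the same clones correlated with r of 0.752, against a median of 0.411 and 0.0938 to 0.635 in 95% of 1000 shuffles of the clones over blocks. With block medians of replicate 2 taken from one part of the clones and those of replicate 4 from the others, r was 0.628, against -0.230 to 0.257 in the shuffles. This argues against strychnine as the whole cause, if clones of a block are otherwise unrelated (genes of one fixed list shared a block in 3.41% of pairs, within the shuffled range of 1.95% to 4.06%), and position on the slide is a candidate explanation for part of the agreement. After block medians and the local trend were removed, r across genes was still 0.331, and whether that part may hold an effect of strychnine cannot be told apart from dye effects of single genes, because the direction of the columns is not stated and intensities were not used here.

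The 11 units called in the planned contrast may come from single aberrant spots: 9 of the 11 rested, on their extreme array, on 1 spot or on duplicates over 1 log2 unit apart. The exceptions were 7B2 and an unnamed pair, both judged on replicate 4. On replicate 2 the spots of that unnamed pair lay apart, at 1.297 and 4.714. Of the 3 ways to set one distinct set against another, 1 gave as many calls, the real one, and the highest other count was 0. So few splits cannot give a share under 0.05. Both spots of 7B2 were low on replicate 4 (-4.307 and -3.539) and near 0 on replicate 2 (-0.052 and -0.006), so its call rests on 1 array with no further array to check it.

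For the 350 units that ran the same way in the centred sets, position bias as the whole cause would have removed most of their size. Their median absolute mean log2 ratio went from 1.07 to 0.550 after the position correction, which is 0.512 of its size, with a 95% interval of 0.484 to 0.558 over 1000 resamples of these units, added after the result was seen. Set beforehand were a bound of 0.5, above which position would not be the whole cause, and a lower bound, under which it would be. The value lay just above the first and did not fall under the second. The resampled units share the same 3 sets, so the interval leaves out the spread between arrays, and it still takes in 0.5. These units were also picked for their means before the correction, so some loss of size could follow whatever the cause. Position as the whole cause is therefore neither excluded nor borne out. Of the 350, 348 kept their sign and 0 remained past the threshold. Their median SD went from 0.316 to 0.274, the median SE of all units from 0.214 to 0.141, and the prior degrees of freedom from 4.97 to 3.09. Which of these changes ended the calls was not separated. Of 4 sign patterns of the 3 sets, 1 gave as many calls, the real one at 350 with 0 as the highest other, and 4 patterns cannot give a share under 0.05. Position, gene-specific dye effects and an effect of strychnine all stay open.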
